A study of Mus musculus with 22 samples.

How the data were processed

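Bulk RNA sequencing was performed on first mandibular molars of mice at postnatal day 5 (P5) and postnatal day 11 (P11). Mice carried either 1 mutated copy of Tgfbr2, in which a glycine of the receptor is replaced by tryptophan (Het), or 2 unmutated copies (WT, littermates). The mutation models Loeys-Dietz syndrome, an inherited connective tissue disorder caused by altered TGF-beta signalling. The 22 libraries comprised 6 P5 WT, 6 P5 Het, 5 P11 WT and 5 P11 Het samples. Per the labels' protocols, total RNA was extracted with TriPure reagent and silica columns, Nextera XT libraries without strand information were prepared, and paired-end reads of 100 bases were obtained over separate runs of an Illumina instrument. Without strand information, reads of overlapping or antisense genes cannot be told apart. Nextera XT carries no molecular identifiers, so reads are not independent molecules and counting intervals cover counting error only.

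Groups were taken from the sample titles. One library, P5 Het replicate 6, is named P5 in its title and library name while its tissue and treatment fields name P11. It was kept in the P5 Het group, and every comparison was repeated without it. The series text counts 5 Het and 8 WT mice, fewer than the 22 libraries, so some libraries may come from the same animal and the p-values may then be too small. Nothing in the labels ties a library to an animal, and the p-values measure the spread between libraries. All libraries carry 1 batch label. The library names contain a number ahead of a hyphen, called the prefix here, which is 3, 4 or 5 at P5 and 1 or 2 at P11 and whose meaning is not given in the labels. Prefix 5 belongs only to P5 Het 5 and 6, so with the prefix as a block these libraries add nothing to the genotype effect at P5, which then rests on the other 4 P5 Het libraries.

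Per the submitters' processing notes, STAR 2.7.3a, DESeq2, edgeR and limma were used with the mouse genome build GRCm38, and the role of the last 3 tools is not given. The read counter and gene annotation are not given in the sources used here. The deposited raw table holds whole-number counts per gene for 55439 features, of which 18 are sequences that are not mouse genes, such as transgenes. These took between 0.000109% and 0.000457% of each library and were left out. A second deposited table holds the same counts for 28711 features, which are those with more than 5 counts in at least 1 library. The deposited normalised values (unit: signal) are those counts divided by library sizes that the authors scaled by TMM, the trimmed mean of M values, and expressed as CPM, counts scaled to a common library total. The scale factors recomputed from the counts differed from the deposited ones by at most 3.3e-16 in relative terms. The normalised table was used for gene symbols and for that check only.

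All tests used the raw counts. Library totals ranged from 32904047 to 45343814 counts. A filter on low counts (filterByExpr with a minimum count of 10 and a minimum total of 15) left 21510 genes, and 21477 of their identifiers matched the GENCODE M21 annotation of GRCm38, from which coordinates were taken. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM factors and 4 age-by-genotype groups in a model of all 22 libraries, which left 18 residual degrees of freedom. The common dispersion was 0.0381. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and adjusted p-values in the text come from this test unless another is named. Values in CPM in the text are TMM-scaled group means with the SD between libraries. Log2 fold changes carry an approximate standard error (SE). It is the size of the log2 fold change divided by the square root of the F statistic of the test. Where a group holds few counts this SE can be too small. No pair of replicate libraries was close enough to be a single library deposited again: the chi-square of their counts per degree of freedom ran from 6.94 to 101. Sex was read from Y-linked genes, with male libraries above 10 CPM. The P5 WT group held 3 males and 3 females, P5 Het 4 and 2, P11 WT 2 and 3, and P11 Het 2 and 3.

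The comparisons were Het versus WT at P5, at P11 and as the mean of both ages, the genotype by age interaction (the effect at P11 minus that at P5), and P11 versus P5 within each genotype. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run beside it. The 24 tested lists covered TGF-beta targets, TGF-beta pathway components, BMP signalling, Wnt targets, secretory-stage enamel, maturation-stage enamel, odontoblast and dentin, pulp and follicle mesenchyme, dental epithelium, fibrous extracellular matrix, adhesion and basement membrane, cell cycle, endoplasmic reticulum stress, immediate early stress, muscle, erythroid cells, myeloid and immune cells, osteoclasts, osteoblasts and bone, cartilage, endothelium and mural cells, nerve and Schwann cells, oral keratinocytes and iron genes. Lists for salivary gland and adipose tissue had fewer than 5 tested members and were not tested.

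The rule for naming genes was as follows. Tgfbr2 came first. For each genotype comparison and the interaction, the 10 largest changes in each direction among called genes with a mean log2 CPM above 0 could be named, and the 5 smallest p-values where fewer than 5 genes were called. For the age comparisons the minimum was a mean log2 CPM of 3. Up to 4 members of each list with the smallest p-values, and any member of the enamel and TGF-beta component lists, could be named as well. Predicted genes, pseudogenes, Xist and the Y-linked genes used to read sex were counted but not named.

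Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts (44963 genes), the compared groups fitted alone, the replicate number or the library-name prefix as a block, sex as a covariate, and each library left out in turn. The comparisons, tests, lists, naming rule and these alternatives were fixed before the data were examined. After scores of the marker lists had been seen, 2 more were added: leaving out libraries with raised muscle or oral mucosa markers (a mean log2 CPM of either list more than 1 above the median of the age), and both marker scores as covariates.

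The procedure was tested on simulated data with 200 genes changed in counts drawn from the real means and library sizes. Each gene was drawn independently, with the same change at both ages and no structure from prefixes, neighbouring tissue or shared animals. The shares below hold for such data, and false calls may be more frequent in the real libraries. At P5, 31.8%, 67.2% and 82.1% of genes changed by a log2 value of 0.5, 1 and 2 were recovered among 21510 genes, and 3.97% of calls were false. At P11 the shares were 30.3%, 68.7% and 88.1%, with 6.72% false calls. For the mean of both ages they were 48.5%, 77.6% and 94%, with 5.77% false calls.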

Results

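Gene expression was measured in whole first mandibular molars of Tgfbr2 mutant mice (Het) and WT littermates at P5, when ameloblasts secrete the enamel matrix, and at P11, when the enamel matures. The 22 libraries held between 32904047 and 45343814 counts. Mean totals were 38280092 ± 2018790 in P5 WT and 36947256 ± 2847985 in P5 Het (SD, n = 6 each), and 37920085 ± 1777761 in P11 WT and 42636617 ± 2383516 in P11 Het (SD, n = 5 each). The first principal component took 77.4% of the variance of the 1000 most variable genes and separated P5 from P11 libraries. The library whose labels disagree on its age, P5 Het replicate 6, had a score of -47.9 on it. The other P5 libraries lay between -48 and -40.8 and the P11 libraries between 44.1 and 75.7.

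**Figure D1:**
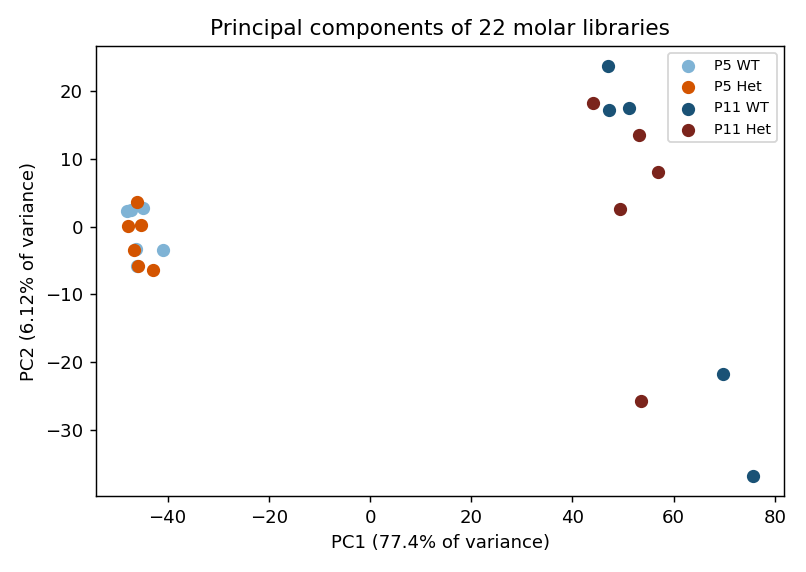
Principal component scores of the 22 libraries, computed on the log2 CPM of 1000 genes, with the share of variance (77.4% and 6.12%) on each axis. Each point is 1 library, coloured by age and genotype; P5 libraries lie on the left and P11 libraries on the right, and WT and Het points of an age overlap.

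Markers of tissues around the tooth differed between libraries. Oral keratinocyte markers, given as the mean log2 CPM of the list, stood at 6.44 in P11 WT 4, 5.22 in P11 WT 5 and 5.60 in P11 Het 2. No other P11 library was above 2.90. Krt4, a keratin of the oral mucosa, was at 305, 81 and 271 CPM in those 3 libraries and between 0.541 and 17.2 CPM in the other P11 libraries. Muscle markers reached 2.65 in P11 Het 2 and 1.63 in P5 Het 5, where the other P5 libraries lay between -1.16 and -0.44. Oral keratinocyte markers were at 0.26 in P5 Het 4 and between -1.31 and -0.70 in the other P5 libraries. These 5 libraries were left out in one of the alternatives, which left 6 P5 WT, 4 P5 Het, 3 P11 WT and 4 P11 Het libraries.

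**Figure D2:**
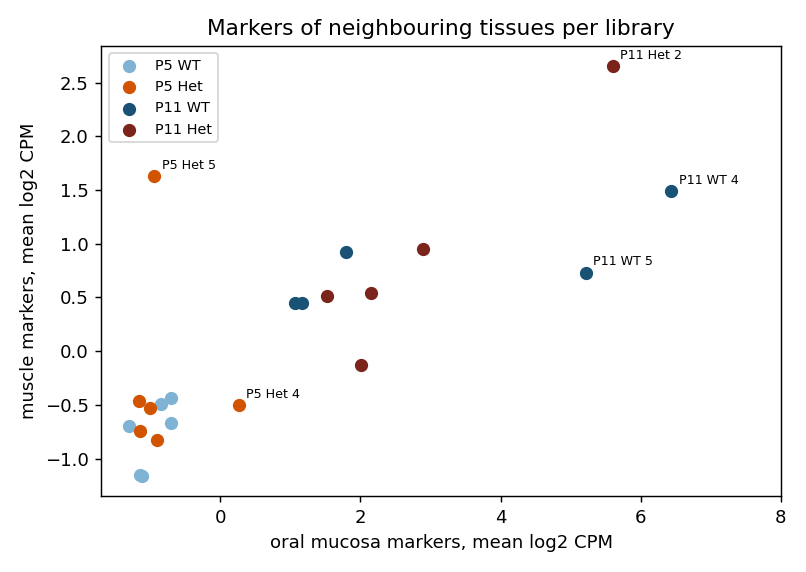
Mean log2 CPM of the oral mucosa (oral keratinocyte) markers on the horizontal axis against the mean log2 CPM of the muscle markers on the vertical axis. Each point is 1 library, coloured by group, and the 5 labelled libraries lie more than 1 above the median of their age on either axis.

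Tgfbr2, the gene that carries the mutation, encodes the type II TGF-beta receptor (ENSMUSG00000032440; GRCm38, chromosome 9, 116084293 to 116175360). Its level was 180 ± 13.5 CPM in P5 WT and 186 ± 18 CPM in P5 Het molars (SD, n = 6 each), a log2 fold change of 0.05 ± 0.07 (SE; adjusted p = 0.959). At P11 it was 112 ± 4.76 CPM in WT and 105 ± 6.43 CPM in Het molars (SD, n = 5 each), a log2 fold change of -0.09 ± 0.07 (SE; adjusted p = 0.725). A point mutation need not alter the transcript level, so these values do not check the genotype labels. With age Tgfbr2 fell by 0.68 ± 0.07 on the log2 scale in WT (SE; adjusted p = 1.54e-08) and by a log2 fold change of -0.82 ± 0.07 in Het molars (SE; adjusted p = 8.51e-10).

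The comparison of Het and WT molars at P5 asks which genes the mutation alters during the secretory stage. Steap1, which encodes a membrane protein of the metalloreductase family (ENSMUSG00000015652; chromosome 5, 5736317 to 5749326), gave the smallest p-value. It fell from 58.4 ± 4.56 CPM in WT to 23.6 ± 2.56 CPM in Het molars (SD, n = 6 each), and all 6 Het libraries (20.4 to 27.4 CPM) lay below all 6 WT libraries (52.8 to 63.4 CPM). Its log2 fold change was -1.31 ± 0.11 (SE; adjusted p = 6.49e-07). Crhr1, the receptor of corticotropin-releasing hormone, fell from 6.63 ± 1.2 to 1.8 ± 0.34 CPM (SD, n = 6 each; log2 fold change -1.88 ± 0.28 SE, adjusted p = 0.00241). Gpr4, a proton-sensing receptor, fell from 41.8 ± 2.65 to 21.4 ± 1.92 CPM (SD, n = 6 each; adjusted p = 0.00198). Plppr4, a member of the lipid phosphatase-related family known from neurons, rose from 20.9 ± 2.28 to 39.4 ± 4.04 CPM (SD, n = 6 each; log2 fold change 0.92 ± 0.10 SE, adjusted p = 2.49e-05).

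In all, 14 genes were higher and 42 lower in P5 Het molars at an adjusted p under 0.05, of 21510 tested. Among those higher were the orphan receptor Gpr165 with a log2 fold change of 1.30 ± 0.20 (SE), the thyroid hormone-activating deiodinase Dio2 with 1.14 ± 0.20 and the membrane glycoprotein Gpnmb with 0.98 ± 0.18. Also higher were the collagens Col20a1 (0.65 ± 0.11) and Col25a1 (0.59 ± 0.11), the inositol phosphatase Inpp5j (0.65 ± 0.13), the cadherin Cdh23 (0.49 ± 0.08) and the actin-binding coronin Coro6 (0.47 ± 0.08). Among those lower were the activin-binding protein Fst (log2 fold change -1.05 ± 0.20 SE), the immunoglobulin light chain Igkc (-1.19 ± 0.21) and the delta opioid receptor Oprd1 (-1.62 ± 0.33). The complement regulator Cd55 (-0.81 ± 0.10) and the milk protein gene Csn3 (-2.28 ± 0.49) were lower too. Reads of Cd55 and its near-identical neighbour Cd55b may be shared, and the values of immunoglobulin genes are uncertain for the same reason. The collagenase Mmp13 fell by 0.60 ± 0.11 and the TGF-beta-activating thrombospondin Thbs1 by 0.53 ± 0.09 on the log2 scale (SE). The pyrophosphate-generating enzyme Enpp1 fell by 0.65 ± 0.13 and Lama3, a laminin chain of the epithelial basement membrane, by 0.32 ± 0.05 on the log2 scale (SE).

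**Figure D3:**
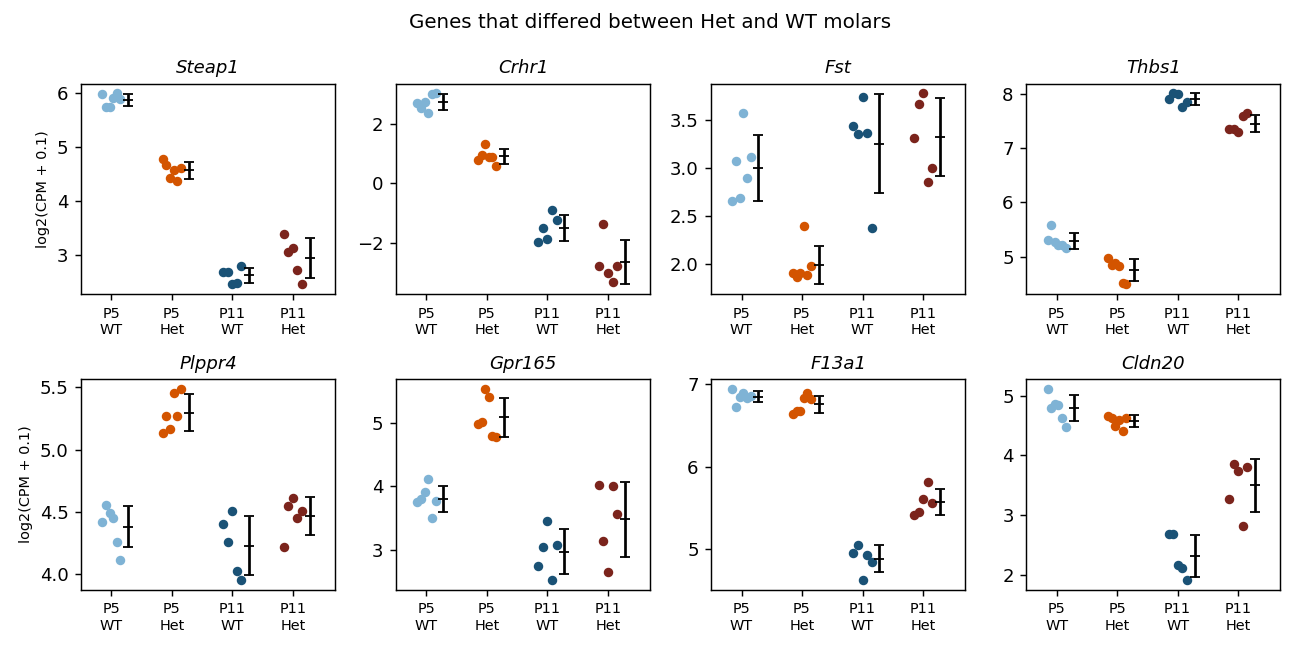
Log2(CPM + 0.1) of 8 genes called between Het and WT molars in at least 1 comparison. Each point is 1 library, and the bar beside each group gives the mean and SD (n = 6 at P5, n = 5 at P11); Steap1, Crhr1, Fst and Thbs1 were lower and Plppr4 and Gpr165 higher in P5 Het molars, while F13a1 and Cldn20 were higher in P11 Het molars.

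Klk4, the protease that removes the enamel matrix (ENSMUSG00000006948; chromosome 7, 43881160 to 43885804), was at 8.24 ± 1.56 CPM in WT and 4.79 ± 0.9 CPM in Het molars (SD, n = 6 each; log2 fold change -0.78 ± 0.16 SE, adjusted p = 0.0284). Of the 27 tested members of the maturation list, 17 had a negative and 10 a positive log2 fold change, with a median of -0.07. Over all genes 1 was called higher and 1 lower; adjusted over the list alone 2 were higher and 5 lower. The 5 were Klk4, the calcium exchanger Slc24a4 (-1.52 ± 0.37 SE), the enamel phosphoprotein gene Odaph (-1.08 ± 0.25) and the enamel matrix proteins Amtn (-1.22 ± 0.34) and Odam (-0.50 ± 0.16). The monocarboxylate transporter Slc5a8 was higher, at a log2 fold change of 2.21 ± 0.45 (SE; adjusted p = 0.0268). With the library-name prefix as a block, Slc24a4 (-1.79 ± 0.26 SE, adjusted p = 0.00186), Odaph (-1.40 ± 0.23, 0.00767), Amtn (-1.64 ± 0.29, 0.0108) and Odam (-0.65 ± 0.10, 0.00407) were lower over all genes as well. The list was lower by camera (adjusted p = 0.049), and its adjusted p was 0.619 with an estimated correlation, 0.557 with fry and 0.14 with the muscle and oral mucosa scores as covariates. The secretory list was also lower (adjusted p = 0.0465; adjusted p = 0.573 with an estimated correlation), with Lama3 the member called over all genes and adjusted over the list alone. The main secretory matrix genes Enam (-0.08 ± 0.61), Amelx (0.13 ± 0.33) and Ambn (-0.22 ± 0.17) were not called at P5 (SE; adjusted p = 0.991, 0.977 and 0.928).

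**Figure D4:**
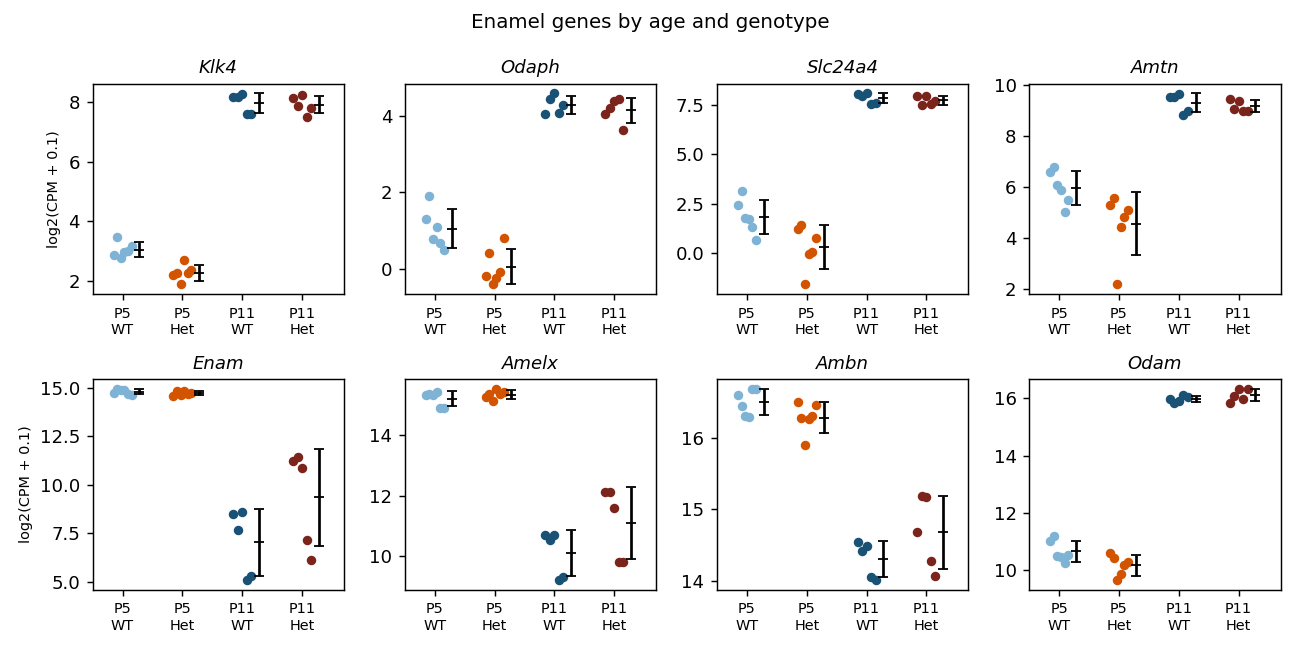
Log2(CPM + 0.1) of 8 enamel genes by age and genotype. Each point is 1 library, and the bar beside each group gives the mean and SD (n = 6 at P5, n = 5 at P11); the maturation genes Klk4, Odaph, Slc24a4 and Amtn were low at P5 and high at P11, and Enam and Amelx were high at P5 and spread widely between P11 libraries.

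Of 29 tested cell cycle genes 26 had a negative log2 fold change at P5, with a median of -0.20, and 8 were lower adjusted over the list alone, though none over all genes. Examples are Top2a, which untangles replicated DNA (-0.25 ± 0.06 SE, adjusted p = 0.0716), and Mcm5 of the replicative helicase (-0.23 ± 0.06 SE, adjusted p = 0.217). The list was lower by camera (adjusted p = 7.06e-10), and the adjusted p was 0.0757 with an estimated correlation and 0.0221 with fry. Endoplasmic reticulum stress genes had negative values in 21 of 24 members, none called over all genes (median -0.12; camera adjusted p = 0.000103, and adjusted p = 0.153 with an estimated correlation), with Chac1, a glutathione-degrading enzyme of the stress response, at -0.41 ± 0.09 (SE; adjusted p = 0.0533).

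TGF-beta targets had negative values in 19 of 30 members at P5 (median -0.07; camera adjusted p = 0.0211, and adjusted p = 0.3 with an estimated correlation). Thbs1 was lower over all genes, and Pmepa1, a feedback inhibitor of the pathway, joined it adjusted over the list alone (-0.48 ± 0.12 SE, adjusted p = 0.101 over all genes). Pulp and follicle mesenchyme (median -0.07) and fibrous matrix genes (median -0.04) were lower by camera, at adjusted p = 0.0251 and 0.0271; with an estimated correlation the adjusted p-values were 0.3 and 0.573. The elastic fibre gene Fbln5 (-0.29 ± 0.07 SE) was the matrix member called adjusted over the list alone. Muscle markers were higher (median 0.99, 15 of 17 members positive; adjusted p = 0.00455, and adjusted p = 0.608 with an estimated correlation). Embryonic and perinatal myosin Myh8 was at 19.9 CPM in P5 Het 5 and at most 0.655 CPM in the other P5 libraries, and was the muscle gene called adjusted over the list alone. Endothelial and mural genes were higher (median 0.06; adjusted p = 0.0267, and adjusted p = 0.573 with an estimated correlation), 3 of 22 adjusted over the list alone. Without the libraries with raised muscle or oral mucosa markers the muscle, pulp, matrix and endothelial lists were not called (adjusted p = 0.243, 0.154, 0.0553 and 0.0553). With the prefix block the muscle and endothelial lists were not called (adjusted p = 0.467 and 0.281). With the muscle and oral mucosa scores as covariates the adjusted p of the TGF-beta targets was 0.0529, that of the endothelial list 0.0893 and that of the matrix list 0.0994. Without P5 Het 6 that of the matrix list was 0.0535.

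Of the 9 lists called by camera at P5, fry called 1, the cell cycle list. The other lists were not called at P5: odontoblast and dentin (median -0.05; adjusted p = 0.19), adhesion and basement membrane (-0.02; 0.181), dental epithelium (0; 0.753), Wnt targets (0; 0.804) and immediate early stress (-0.04; 0.872). Nor were erythroid cells (median 0.18; adjusted p = 0.0664), osteoclasts (-0.02; 0.761), cartilage (-0.12; 0.181), nerve and Schwann cells (-0.04; 0.761) and oral keratinocytes (0.34; 0.804). Cldn1, a tight junction protein on the epithelium and adhesion lists, stood at -0.64 ± 0.15 (SE; adjusted p = 0.0768) and was lower adjusted over either list alone. BMP signalling was not called either (median 0; adjusted p = 0.804). Single members of uncalled lists were lower over all genes: Fst of the TGF-beta components and BMP lists, Enpp1 of the odontoblast list, Lama3 of the adhesion list and Mmp13 of the bone list. For 4 lists the median, mean and test did not share a sign. They were TGF-beta components (median 0, mean 0, test up, adjusted p = 0.839), myeloid and immune cells (0, 0.10, down, 0.761), osteoblasts and bone (-0.06, 0.01, down, 0.34) and iron genes (0, 0.01, down, 0.839).

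**Figure D5:**
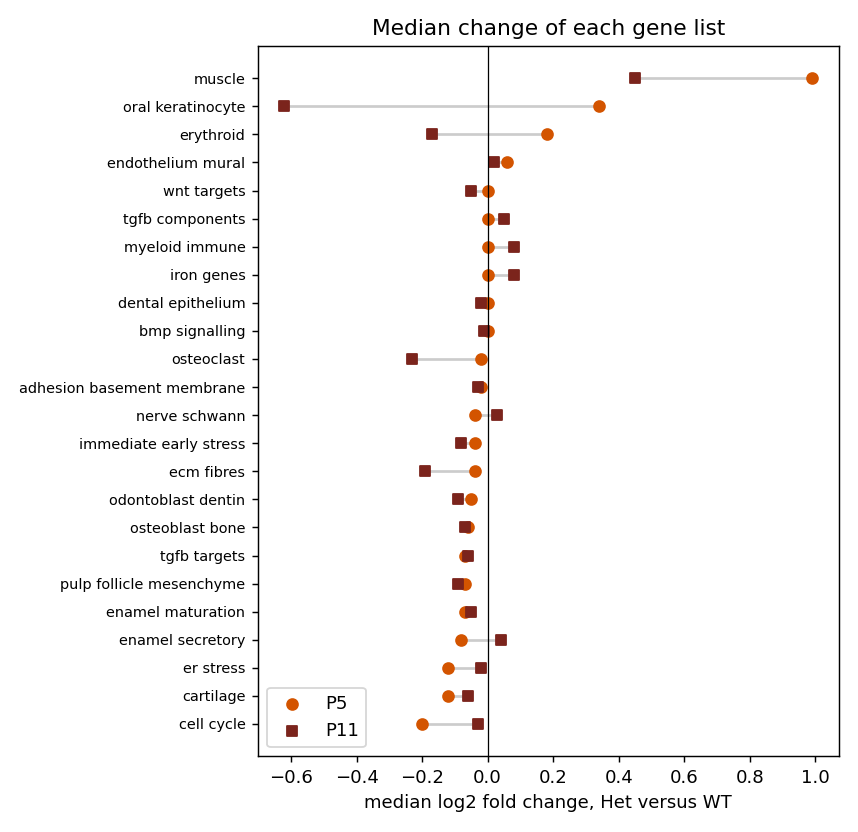
Median log2 fold change of each tested gene list between Het and WT molars at P5 (circles) and P11 (squares), joined by a grey line. Each list has its own line on the vertical axis and 0 is marked; cell cycle genes had a median of -0.20 at P5 and -0.03 at P11, and fibrous matrix genes -0.04 and -0.19.

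With the library-name prefix as a block, 20 genes were higher and 49 lower at P5, and DESeq2 called 43 and 90. Without the libraries with raised muscle or oral mucosa markers the counts were 9 and 11. Lost there were the calls of Thbs1 and Mmp13 (adjusted p = 0.0673 for both), Lama3 (0.0664), Coro6 and Gpnmb (0.0573 for both), Igkc (0.0926), Enpp1 (0.134), Csn3 (0.291) and Slc5a8 and Oprd1 (0.0673 for both). Other settings ended the calls of Gpnmb and Slc5a8 (0.186 and 0.257 with limma-voom, 0.0598 and 0.12 with the P5 groups alone), Oprd1 (0.0808 with the prefix block), Enpp1 (0.105 with the P5 groups alone, 0.0679 with the marker scores as covariates), Fst (0.0885 with limma-voom) and Csn3 (0.0543 with the marker scores as covariates). The number lower was 27 without P5 Het 4, 25 without P5 Het 5 and 26 without P5 Het 6. Klk4 lost its call without P5 WT 2, 5 or 6 or without P5 Het 1, 2, 3, 5 or 6 (adjusted p = 0.0551 to 0.102) and with limma-voom (0.373). Fst lost it without P5 WT 4 or P5 Het 1, 2, 5 or 6 (0.0501 to 0.0568) and Enpp1 without P5 WT 4, 5 or 6 or P5 Het 1, 2 or 5 (0.0588 to 0.0777). Oprd1 lost it without P5 WT 2, 5 or 6 or P5 Het 1, 2, 4 or 6 (0.0584 to 0.0893). Slc5a8 lost it without P5 WT 1, 2, 4 or 5 or P5 Het 1, 2, 3 or 4 (0.0549 to 0.0893) and Inpp5j without P5 WT 1, P5 Het 2 or P5 Het 4 (0.053 to 0.0547). Csn3 kept its call in 10 of the 22 omissions. These were those of P5 WT 5 or 6, P5 Het 1 or 3, P11 WT 4 or 5, and P11 Het 2, 3, 4 or 5; its adjusted p rose to at most 0.126 in the others.

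At P11 the comparison of genotypes covers the maturation stage. F13a1, the catalytic subunit of the transglutaminase factor XIII, was at 29.6 ± 3.22 CPM in WT and rose to 47.7 ± 5.34 CPM in Het molars (SD, n = 5 each; log2 fold change 0.69 ± 0.08 SE, adjusted p = 0.000241). The claudin Cldn20 rose from 4.99 ± 1.26 to 11.6 ± 3.23 CPM (SD, n = 5 each; log2 fold change 1.22 ± 0.17 SE, adjusted p = 0.00448). Frmd7, a cytoskeletal scaffold protein, rose by 1.00 ± 0.17 (adjusted p = 0.0198) and the endocytic protein Ehd3 by 0.37 ± 0.07 (SE; adjusted p = 0.0416) on the log2 scale. The metalloprotease Adamts16 fell from 4.14 ± 0.829 to 1.33 ± 0.271 CPM (SD, n = 5 each; log2 fold change -1.63 ± 0.28 SE, adjusted p = 0.0312). These and 1 predicted gene made up the 5 genes higher and 1 gene lower by edgeR.

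Of 34 fibrous matrix genes, 24 had a negative log2 fold change in P11 Het molars, with a median of -0.19. Of these, 6 collagen and crosslinking genes were lower adjusted over the list alone, and none over all genes. Among them were the fibril collagens Col5a1, at 248 ± 25.6 CPM in WT and 183 ± 12.7 CPM in Het molars, and Col12a1, at 1540 ± 191 and 1130 ± 242 CPM (SD, n = 5 each). Their log2 fold changes were -0.44 ± 0.10 and -0.45 ± 0.11 (SE; adjusted p = 0.106 and 0.165). Those of Col6a2 and the collagen crosslinking enzyme Lox were -0.24 ± 0.07 and -0.35 ± 0.11. The list was lower by camera (adjusted p = 1.49e-05), and its adjusted p was 0.369 with an estimated correlation and 0.0607 with fry. TGF-beta targets had negative values in 21 of 30 members (median -0.06; adjusted p = 0.046, and adjusted p = 0.609 with an estimated correlation and 0.298 with fry). Lower adjusted over the list alone were 2 of them, Postn, a matrix protein of the periodontal ligament, at -0.61 ± 0.15 and Thbs1 at -0.45 ± 0.10 (SE; adjusted p = 0.138 and 0.0986). With the library-name prefix as a block Thbs1 (-0.45 ± 0.07 SE, adjusted p = 0.00665), Postn (-0.63 ± 0.11, 0.0101), Col12a1 (-0.46 ± 0.08, 0.00753) and Col5a1 (-0.44 ± 0.09, 0.0432) were lower over all genes. No other list was called at P11, the next smallest adjusted p being 0.205 for osteoclast genes (median -0.23).

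Of the 24 secretory enamel genes, 16 had a positive and 8 a negative log2 fold change at P11. Enam, the enamelin gene (ENSMUSG00000029286; chromosome 5, 88487975 to 88506049), was at 203 ± 168 CPM in WT and 1430 ± 1250 CPM in Het molars (SD, n = 5 each; log2 fold change 2.81 ± 0.72 SE, adjusted p = 0.16). The values followed the library-name prefix. Among the libraries with prefix 1, Enam was at 356, 200 and 388 CPM in WT and at 2370, 2710 and 1860 CPM in Het molars. Among those with prefix 2 it was at 33.6 and 39.7 CPM in WT and at 141 and 70.3 CPM in Het molars. With the prefix as a block its log2 fold change was 2.35 ± 0.24 (SE; adjusted p = 8.97e-05). Amelx, the amelogenin gene, was at 1210 ± 546 CPM in WT and 2750 ± 1780 CPM in Het molars (SD, n = 5 each; adjusted p = 0.314), and its adjusted p with the block was 0.00213. Adjusted over the secretory list alone, Enam, Amelx and the transcription factor gene Dlx3 (0.60 ± 0.18 SE) were higher; the list test gave an adjusted p of 0.305. Ambn (0.43 ± 0.18 SE, adjusted p = 0.451) was not called. Of the maturation genes, Klk4 stood at -0.06 ± 0.16 (adjusted p = 0.934) and Odam at 0.15 ± 0.18 (SE; adjusted p = 0.829).

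Of the dental epithelium list, 3 members were higher adjusted over the list alone: the signalling ligand Shh (1.66 ± 0.51 SE), the claudin Cldn10 (1.01 ± 0.22) and the lysophospholipase Enpp2 (0.58 ± 0.15), at adjusted p = 0.309, 0.0986 and 0.16 over all genes. With the prefix block Cldn10 (0.98 ± 0.12 SE, adjusted p = 0.000327) and Enpp2 (0.59 ± 0.08, 0.000576) were called. The list as a whole was not called (median -0.02, mean 0.03, test down; adjusted p = 0.905). The maturation list had a median of -0.05 and a mean of -0.03 while its test pointed up (adjusted p = 0.85). Tgfbr3, the betaglycan co-receptor of TGF-beta, stood at 0.68 ± 0.19 (SE; adjusted p = 0.255) and was higher adjusted over the list of components alone, whose test gave an adjusted p of 0.224. The Wnt effector Lef1 stood at 0.35 ± 0.08 (SE; adjusted p = 0.106). Oral keratinocyte markers had a median of -0.62 (adjusted p = 0.305) and all 18 tested members had negative values, with 2 of the 3 libraries rich in these markers in the WT group. The direction turned when the libraries with raised markers were left out, and the list was then higher in Het molars (adjusted p = 7.81e-05). Muscle markers had a median of 0.45 (adjusted p = 0.463).

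The count at P11 depended on the treatment of the data. At an unadjusted p under 0.05 there were 2119 genes. With the library-name prefix as a block 47 genes were higher and 38 lower, and DESeq2 called 70 and 37, limma-voom 5 and 15, and edgeR on the P11 groups alone 0 and 1. Without the libraries with raised muscle or oral mucosa markers 2 were higher and 2 lower. Cldn20, Frmd7 and Ehd3 were then no longer called (adjusted p = 0.243, 0.0619 and 0.489). On the P11 groups alone F13a1 had an adjusted p of 0.0815, Cldn20 and Ehd3 of 0.22 and Frmd7 of 0.337; that of Ehd3 was 0.0511 with RLE size factors and 0.0861 with no filter. The number higher was 2 without P11 WT 4, 3 without P11 Het 3, 9 without P11 Het 1, 14 without P11 Het 4 and 19 without P11 Het 5. The number lower was 0 without P11 WT 2, 3 or 4 or P11 Het 3, and 2 without P5 WT 4, P11 WT 1 or P11 Het 2. It was 3 without P5 WT 5, P5 WT 6 or P11 WT 5, 4 without P11 Het 1 or 4, and 7 without P11 Het 5. Adamts16 lost its call without P11 WT 1, 2, 3 or 4 or P11 Het 2 or 3 (adjusted p = 0.0629 to 0.0847), and Frmd7 without P11 WT 1, 3 or 4 or P11 Het 3 (0.0506 to 0.0761). Ehd3 kept its call in 8 of the 22 omissions, those of P5 WT 6, P5 Het 3 or 5, P11 WT 1 or 2 and P11 Het 1, 4 or 5. Its adjusted p reached 0.16 in the others.

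The mean genotype effect over both ages averages the effects at P5 and P11, so a gene altered at 1 age can pass as well. Thbs1 fell by 0.49 ± 0.07 on the log2 scale (SE; adjusted p = 0.00153). It was at 39.3 ± 4.45 CPM in WT and 27.2 ± 3.68 CPM in Het molars at P5 (SD, n = 6 each), and at 240 ± 17.7 and 176 ± 19.1 CPM at P11 (SD, n = 5 each). The short-chain collagen Col8a1 fell by 0.60 ± 0.09 (SE; adjusted p = 0.00356), from 9.58 ± 1.3 to 6.57 ± 0.714 CPM at P5 (SD, n = 6 each) and from 27.4 ± 2.67 to 17.4 ± 3.9 CPM at P11 (SD, n = 5 each). The secreted protein C1qtnf7 (-0.44 ± 0.07 SE), Adamts16 (-1.26 ± 0.20), Crhr1 (-1.77 ± 0.29), Steap1 (-0.47 ± 0.08) and Lama3 (-0.22 ± 0.04) were lower as well, Steap1 with effects that differed between the ages (an interaction of 1.66). Higher were Plppr4 (log2 fold change 0.57 ± 0.07 SE, adjusted p = 0.00102), Gpr165 (0.93 ± 0.15), the hyaluronidase family member Hyal4 (0.50 ± 0.08), Col25a1 (0.43 ± 0.08) and Otos (1.45 ± 0.28). Also lower were the secreted Wnt modulator Sfrp2 (-0.63 ± 0.13), the extracellular peroxidase Gpx3 (-0.46 ± 0.09) and the neuropeptide gene Gal (-0.88 ± 0.18). In all, 14 genes were higher and 23 lower.

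Matrix, TGF-beta and cell cycle lists were lower in the mean of both ages, which does not mean that each was lower at both. Fibrous matrix genes had negative values in 23 of 34 members (median -0.10), with 11 lower adjusted over the list alone and none over all genes, Fbln5 being the member with the smallest p (-0.24 ± 0.05 SE, adjusted p = 0.0611 over all genes). The camera test gave an adjusted p of 1.31e-07 for this list and the same for cell cycle genes, and for both the adjusted p was 0.0661 with an estimated correlation and 0.027 with fry. In the cell cycle list 26 of 29 members were negative (median -0.12), and Top2a stood at -0.14 ± 0.04 (SE, adjusted p = 0.271). This list had a median of -0.20 at P5. At P11 alone its median was -0.03 and it was not called (camera adjusted p = 0.305). The matrix list leaned the other way, with medians of -0.04 at P5 and -0.19 at P11. TGF-beta targets had 21 of 30 negative members (median -0.08; adjusted p = 0.000201, and again adjusted p = 0.0661 with an estimated correlation and 0.027 with fry), with Thbs1 lower over all genes and Postn (-0.34 ± 0.10 SE, adjusted p = 0.286) and Pmepa1 (-0.29 ± 0.09 SE, adjusted p = 0.286) besides it adjusted over the list alone. The TGF-beta targets and the matrix list share members, and Thbs1 is a target that is not on the matrix list.

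Of the 9 lists called by camera over both ages, fry called those 3. Smaller list effects had adjusted p-values by camera of 0.00323 for endoplasmic reticulum stress (median -0.05), 0.00723 for pulp and follicle mesenchyme (-0.08), 0.0224 for adhesion and basement membrane (-0.05) and 0.0418 for odontoblast and dentin genes (-0.05), all lower. With an estimated correlation the adjusted p-values were 0.204, 0.183, 0.204 and 0.301. Muscle (median 0.81; adjusted p = 0.00723) and endothelial and mural genes (0.04; adjusted p = 0.0372) were higher, with adjusted p = 0.566 and 0.51 with an estimated correlation. Without the libraries with raised muscle or oral mucosa markers the adjusted p-values of the adhesion, muscle and endothelial lists were 0.226, 0.747 and 0.158. With the prefix block those of the muscle and endothelial lists were 0.245 and 0.163. With the marker scores as covariates those of the odontoblast, muscle and endothelial lists were 0.0775, 0.478 and 0.0927, and without P5 Het 6 that of the odontoblast list was 0.0773. Oral keratinocyte markers (median -0.24; adjusted p = 0.459) turned direction without the libraries with raised markers and were then higher in Het molars (adjusted p = 0.00352). Klk4 (-0.42 ± 0.11 SE, adjusted p = 0.193) and Enam (1.37 ± 0.46 SE, adjusted p = 0.401) were not called. The secretory enamel list had a median of 0, a mean of 0.07 and a downward test (adjusted p = 0.744), and nerve and Schwann cell genes a median of 0.01, a mean of -0.02 and an upward test (adjusted p = 0.992).

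With the library-name prefix as a block 36 genes were higher and 49 lower over both ages, DESeq2 called 50 and 71, and limma-voom called 9 and 20. Without the libraries with raised muscle or oral mucosa markers 5 were higher and 10 lower. There C1qtnf7 (adjusted p = 0.0637), Hyal4 (0.112), Steap1 (0.163), Lama3 (0.297), Col25a1 (0.163), Otos (0.321), Gal (0.454), Sfrp2 (0.459) and Gpx3 (0.417) were no longer called. With both marker scores as covariates the counts were 7 and 13, and Lama3 (adjusted p = 0.0538), Otos (0.0621), Gal (0.114), Sfrp2 (0.115) and Gpx3 (0.11) were not called. With limma-voom Otos (0.126), Gal (0.237) and Sfrp2 (0.0728) were not called, nor was Lama3 with no filter (0.0743). The number higher was 9 without P5 WT 1 or 2, P5 Het 1, 4 or 5 or P11 Het 2, 8 without P5 WT 5 or P5 Het 6, 7 without P5 WT 3 or P5 Het 2 and 6 without P11 WT 4. The number lower was 15 without P5 Het 2, P11 WT 4, P11 WT 5 or P11 Het 2, 13 without P5 Het 4 or P11 WT 2, 12 without P5 Het 6 and 11 without P5 Het 5. Col25a1 lost its call without P11 WT 4 or 5 (adjusted p = 0.0504 at most). Otos lost it in 11 of the 22 omissions (at most 0.0747), those of P5 WT 3, P5 Het 1, 2, 5 or 6, P11 WT 2, 4 or 5 and P11 Het 1, 2 or 3. Sfrp2 kept its call only without P5 WT 5 or 6, P11 WT 3 or P11 Het 4 or 5 (at most 0.0843 in the other omissions). Gpx3 kept it only without P5 WT 5, P11 WT 1 or 3 or P11 Het 4 or 5 (at most 0.0841), and Gal only without P5 WT 1 or 2, P5 Het 3, P11 WT 1, 2 or 3 or P11 Het 5 (at most 0.0823).

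The genotype by age interaction tests whether the effect at P11 differs from that at P5. Steap1 was lower in Het molars at P5 and stood at 6.08 ± 0.613 CPM in WT and 7.79 ± 1.91 CPM in Het molars at P11 (SD, n = 5 each), an interaction of 1.66 ± 0.17 on the log2 scale (SE; adjusted p = 2.07e-05). F13a1 had an interaction of 0.78 ± 0.11 (SE; adjusted p = 0.00223), with 115 ± 5.61 CPM in WT and 108 ± 7.8 CPM in Het molars at P5 (SD, n = 6 each) against higher Het values at P11. For Cldn20 it was 1.44 ± 0.23 (SE; adjusted p = 0.0151), with 27.7 ± 4.22 and 23.7 ± 1.61 CPM at P5 (SD, n = 6 each). The next smallest p-values, which did not pass, included Csn3 (3.86 ± 0.72 SE) and Cdh23 (-0.64 ± 0.12 SE), both at an adjusted p of 0.0823. Enam (2.90 ± 0.92 SE, adjusted p = 0.369), Klk4 (0.72 ± 0.22 SE, adjusted p = 0.354) and Tgfbr2 (-0.14 ± 0.10 SE, adjusted p = 0.655) were not called.

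These were the 3 genes higher in the interaction by edgeR, which called 0 lower. At an unadjusted p under 0.05 there were 2213 genes. DESeq2 called 41 higher and 15 lower, and limma-voom 3 and 0. The prefix block gave 23 and 6. The number higher was 5 without P5 Het 1, 6 without P5 WT 4, 7 without P11 Het 4 and 8 without P11 Het 5. The number lower was 2 without P5 Het 1 and 1 without P11 WT 1 or P11 Het 1, 3 or 5. Cldn20 had an adjusted p of 0.0512 without P11 WT 4 and 0.527 without the libraries with raised muscle or oral mucosa markers, which left 2 genes higher. No list passed. The smallest adjusted p-values by camera were 0.0504 for cell cycle genes (median 0.16) and 0.0813 for secretory enamel genes (0.15), followed by 0.131 for endoplasmic reticulum stress (0.10), 0.147 for erythroid cells (-0.35) and 0.152 for fibrous matrix genes (-0.09). The list calls in other settings that follow used camera at the preset correlation. With the prefix block the secretory and maturation enamel lists were higher in the interaction (adjusted p = 0.00106 and 0.0296). With an estimated correlation and no block the adjusted p of both was 0.961. That of the cell cycle and oral keratinocyte lists, with all libraries, was 0.961 too. Without the libraries with raised muscle or oral mucosa markers the cell cycle list was higher (adjusted p = 0.000761), and the oral keratinocyte list (median -1.09; adjusted p = 0.454) turned to higher at the same adjusted p. Medians, means and tests differed in sign for BMP signalling (0.02, -0.01, down), myeloid (-0.01, -0.09, up), bone (0, -0.13, up) and cartilage genes (-0.05, -0.06, up). Across the 21510 genes the log2 fold changes at P5 and P11 had a Pearson r of -0.04 and a Spearman rho of -0.10. Genes are not independent replicates, and the effects at the 2 ages share no libraries. Of the 56 genes called at P5, 31 had the same sign at P11 and none was called at both ages. Independent lists would share 0.00325 higher and 0.00195 lower.

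Between P5 and P11 the WT molar passed from enamel secretion to maturation. Enam fell from 28100 ± 2510 CPM (SD, n = 6) to 203 ± 168 CPM (SD, n = 5), a log2 fold change of -7.11 ± 0.87 (SE; adjusted p = 2.83e-07). Amelx fell from 38100 ± 6070 to 1210 ± 546 CPM and Ambn from 93300 ± 11600 to 20400 ± 3430 CPM (SD, n = 6 and 5). Odam rose from 1660 ± 437 to 64300 ± 4680 CPM (SD, n = 6 and 5; log2 fold change 5.28 ± 0.19 SE, adjusted p = 3.91e-16), Klk4 from 8.24 ± 1.56 to 255 ± 55.9 CPM and Amtn from 68.4 ± 29.7 to 654 ± 158 CPM. Of 24 tested secretory genes 17 were lower and 3 higher over all genes (18 and 3 adjusted over the list alone), with a camera adjusted p of 1.06e-07. Of 27 tested maturation genes 24 were higher over all genes and adjusted over the list alone (median 2.47; adjusted p = 4.82e-16).

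In all, 5326 genes were higher and 5307 lower at P11 in WT molars, 2086 and 1794 of them by more than 2-fold. The largest increases included the steroid dehydrogenase Akr1c18, from 0.158 ± 0.122 to 232 ± 29.7 CPM, the peptide transporter Slc15a1, from 0.244 ± 0.174 to 284 ± 48.6 CPM, and the amino acid transporter Slc6a14, from 0.0664 ± 0.0646 to 57.8 ± 8.73 CPM (SD, n = 6 and 5). Ptchd4 (log2 fold change 8.92 ± 0.45 SE) and Triml1 (9.88 ± 0.26) also rose. Triml1 was at 0 to 0.0562 CPM in the P5 WT libraries, so the size of its rise is uncertain. The largest decreases included Otof, a calcium sensor of exocytosis, from 157 ± 19.9 to 0.464 ± 0.211 CPM, the matrix protein Papln, from 936 ± 133 to 7.38 ± 2.12 CPM, and the sulfotransferase Chst1, from 235 ± 11.7 to 3.84 ± 1.62 CPM (SD, n = 6 and 5). Galnt12, which starts mucin-type glycosylation (-6.07 ± 0.35 SE), the catenin Ctnna2 (-4.72 ± 0.41), the tubulin-modifying Ttll11 (-4.64 ± 0.35), the glycoprotein hormone subunit Gpha2 (-4.42 ± 0.32) and Tmem108 (-4.09 ± 0.21) fell as well.

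Mesenchymal and skeletal genes rose with age in WT molars. TGF-beta targets had 18 of 30 members higher and 6 lower over all genes (19 and 7 adjusted over the list alone; median 0.77; adjusted p = 4.5e-05), among them Postn (log2 fold change 4.05 ± 0.16 SE), Thbs1 (2.61 ± 0.10) and Timp3 (2.21 ± 0.09). Fibrous matrix genes had 21 higher and 7 lower of 34, including Col5a1 (2.51 ± 0.10 SE; list median 0.60, adjusted p = 1.33e-05, and adjusted p = 0.0672 with an estimated correlation). Osteoclast genes rose in 12 of 14 members (median 2.48; adjusted p = 7.16e-08), with the acid phosphatase Acp5 up from 9.31 ± 2.53 to 94 ± 16.8 CPM (SD, n = 6 and 5). Bone genes rose in 12 of 17 and fell in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.00105, and adjusted p = 0.143 with an estimated correlation), with Ibsp (2.58 ± 0.20 SE), Mmp13 (3.50 ± 0.12) and the osteopontin gene Spp1 (3.17 ± 0.25) among them. Cell cycle genes rose in 27 of 29 members over all genes and in 28 adjusted over the list alone (median 0.57; adjusted p = 1.17e-08), for example Top2a from 47.1 ± 2.42 to 74.1 ± 2.21 CPM (SD, n = 6 and 5). The maturation, secretory, TGF-beta target, osteoclast and cell cycle calls also passed with an estimated correlation (adjusted p = 0.0277, 0.0294, 0.0277, 0.0277 and 0.0277).

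Markers of mucosa and blood rose too. All 18 tested oral keratinocyte markers were higher over all genes (median 6.57; adjusted p = 6.3e-06, and adjusted p = 0.304 with an estimated correlation; 0.989 with the marker scores as covariates). Values were highest in the 2 WT libraries rich in these markers: Hrnr was at 195 and 32.5 CPM in P11 WT 4 and 5 and at 0 to 1.13 CPM in the other 3. The keratin Krt6b (log2 fold change 9.99 ± 1 SE), the protease Tmprss11d (9.26 ± 1.29), Fam25a (9.45 ± 0.61) and the desmosomal cadherin Dsg3 (5.28 ± 0.19) were among the largest increases. With the marker scores as covariates Krt4 and Hrnr turned direction, to -2.06 and -0.28 from 9.12 ± 2.11 and 10.79 ± 2.40 (SE), and with limma-voom neither was called (adjusted p = 0.286 and 0.24). Tmprss11d stood at 3.69 with the covariates and had an adjusted p of 0.0537 with limma-voom, while Krt6b and Fam25a stood at 6.52 and 7.43 and Dsg3 at 4.78 with the covariates. Erythroid markers rose in 10 of 11 members (median 2.00; adjusted p = 4.5e-05, and adjusted p = 0.143 with an estimated correlation), the globin Hbb-bs from 37.4 ± 9.01 to 163 ± 58.7 CPM (SD, n = 6 and 5). Muscle genes were higher (adjusted p = 0.0102, and 0.485 as the adjusted p with an estimated correlation), and myeloid and immune genes were not called as a list (median 0.69; adjusted p = 0.0563) although Cd74, of antigen presentation, rose by 1.82 ± 0.17 (SE).

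Further lists were higher in WT molars at P11. Immediate early stress genes (median 1.24; adjusted p = 0.000137) and iron genes (0.75; 0.00427) also passed with an estimated correlation (adjusted p = 0.0361 and 0.0277). Endothelial and mural cells (median 0.44; adjusted p = 0.000298), nerve and Schwann cells (1.14; 0.0174) and pulp and follicle mesenchyme (0.41; 0.00405) did not pass with it (adjusted p = 0.107, 0.0795 and 0.0795). Not called were Wnt targets (median 0.45; adjusted p = 0.167), odontoblast and dentin (0.52; 0.199), dental epithelium (0.08; 0.984), adhesion and basement membrane (0.23; 0.199), endoplasmic reticulum stress (-0.11; 0.363) and cartilage (0; 0.984). TGF-beta components (median -0.12, mean 0.08, test down; adjusted p = 0.691) and BMP signalling (median -0.02, mean 0.29, test down; adjusted p = 0.968) had medians and means of opposite sign. The BMP antagonist Grem1 rose by 5.54 ± 0.42 and the Wnt ligand Wnt10b by 4.66 ± 0.20 (SE).

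In Het molars 5250 genes were higher and 5041 lower at P11, 1882 and 1687 of them by more than 2-fold. Enam fell from 26600 ± 1910 to 1430 ± 1250 CPM (SD, n = 6 and 5; log2 fold change -4.22 ± 0.75 SE, adjusted p = 5.86e-05), Amelx by a log2 value of -3.92 ± 0.40 and Ambn by -1.54 ± 0.18 (SE). Klk4 rose from 4.79 ± 0.9 to 245 ± 48.2 CPM (SD, n = 6 and 5; log2 fold change 5.67 ± 0.18 SE), Odam by 5.92 ± 0.20 and Amtn by 4.31 ± 0.39. Akr1c18 (10.63 ± 0.26), Slc15a1 (10.35 ± 0.30), Slc6a14 (10.16 ± 0.39), the annexin Anxa8 (7.79 ± 0.33) and the digestive-type protease Ctrc (10.30 ± 0.35) rose. Ctrc was at 0 to 0.0579 CPM in the P5 Het libraries, so the size of its rise is uncertain. Otof (-6.11 ± 0.61), Papln (-5.34 ± 0.44), Galnt12 (-4.26 ± 0.31) and Wnt3a (-3.71 ± 0.24) fell. Triml1 had 0 counts in all P5 Het libraries and was 1660-fold higher at P11 when set against a floor of 3 counts over the P5 group. Postn rose by 3.50 ± 0.15 and Col5a1 by 2.12 ± 0.10. The mucosal keratins Krt6b (8.98 ± 1.04) and Krt76 (8.67 ± 1.08) (6.82 and 5.89 with the marker scores as covariates) rose with the oral keratinocyte list, of which 18 of 18 members were higher (adjusted p = 2.58e-05, and adjusted p = 0.318 with an estimated correlation).

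Secretory genes were lower in 16 of 24 members and higher in 2, and maturation genes higher in 24 of 27, in Het molars (adjusted p = 2.34e-07 and 1.85e-17, and adjusted p = 0.0346 and 0.0232 with an estimated correlation). Across genes the age effects in WT and Het molars, which share no libraries, had a Pearson r of 0.91 and a Spearman rho of 0.83. They shared 4239 higher and 3911 lower calls, where independent lists would share 1300 and 1240. In all, 6 genes were called in opposite directions. For 5 lists in Het molars the median, mean and test differed in sign. They were TGF-beta components (-0.03, 0.19, down; adjusted p = 0.972), BMP signalling (-0.13, 0.28, down; 0.934) and dental epithelium (-0.10, 0.01, down; 0.776). The others were endoplasmic reticulum stress (-0.06, 0.09, down; 0.824) and cartilage genes (-0.22, 0.12, up; 0.955). Counts of both age comparisons stayed within 1.5 times under every alternative run except the number lower in Het molars with the muscle and oral mucosa scores as covariates, which was 3343. The prefix block was not fitted for the age comparisons.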

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

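The tests of oral mucosa or muscle, bone and TGF-beta response on the matrix genes, the tests of prefix and other tissue on the whole maturation list, the age scores regrouped within prefixes, the splits within prefixes, the settings without libraries with raised markers and the settings with marker scores as covariates were chosen only after the result was seen.

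Of the 27 maturation-stage enamel genes, whose median log2 fold change at P5 was -0.07, 5 were lower and 2 higher adjusted over the list alone, and the 5, picked because they were lower, had a median of -1.08. Picking favours negative medians of the 5 in other settings. These medians were -1.40 with the prefix block, -0.94 without the libraries with raised markers and -1.08 with the marker scores as covariates. Calls over all genes and the whole list are therefore given beside them. The list had a median of -0.07, with 17 negative (camera adjusted p = 0.049 at the preset and 0.619 with an estimated correlation). With the library-name prefix as a block 5 members were lower and 1 higher over all genes. The 5 lower members are the picked ones, so these calls carry the picking too. Without the block 1 was lower and 1 higher. With the block the list was lower at the preset correlation (-0.05, 16 negative, camera adjusted p = 0.00109). This argues against a difference between library-name prefixes as the whole cause. The block was not run with an estimated correlation, with which the list did not pass in the main fit, so that cause is not excluded. Muscle or oral mucosa in some libraries stays open, since only Klk4 was called without those libraries (adjusted p = 0.0209, against 0.545 to 0.877 for the others of the 5), and the list was lower there (-0.10, 18 negative; adjusted p = 0.0435) but not called with marker scores as covariates (-0.05, 16 negative; 0.14). Later developmental timing of Het molars may still account for the pattern: a mean age score over genes outside the enamel lists, set to 0 at the mean of the P5 libraries and 1 at that of the P11 libraries, was -0.003 ± 0.021 in Het and 0.003 ± 0.018 in WT molars at P5 (SD, n = 6 each). The difference of -0.005 (exact permutation p = 0.647 over 924 regroupings, and 0.811 over 90 within prefixes) neither shows nor excludes a delay, nor does that of -0.067 at P11 (exact permutation p = 0.246, and 0.0667 over 120 within prefixes), and a direct effect of the mutation on ameloblasts is open too and was not tested.

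Fibrous matrix genes were lower in Het molars over both ages, with a median log2 fold change of -0.10 (adjusted p = 1.31e-07 at the preset correlation, and adjusted p = 0.0661 with an estimated correlation). With marker scores as covariates, the list's adjusted p of 8.38e-07 argued against less oral mucosa or muscle around Het molars as the whole cause. With the prefix block, an adjusted p of 4.79e-07 argued against a difference between library-name prefixes. Both were at the preset correlation. Neither setting was run with an estimated correlation, with which the list did not pass in the main fit, so neither cause is excluded. At P5 alone the list was not called in either setting on muscle or mucosa markers. Less bone around Het molars stays open, since osteoblast genes had a median of -0.09 and osteoclast genes of -0.12 without passing the test (adjusted p = 0.137 and 0.0718). A lower response to TGF-beta in Het molars is a candidate explanation that stays open too: of the 27 TGF-beta targets outside the matrix list 19 were negative (median -0.08), and adjusted with the other lists they were lower by camera (adjusted p = 0.000184) but not with an estimated correlation (adjusted p = 0.0929). Fewer mesenchymal cells would lower the same genes, and the lower pulp and follicle list (adjusted p = 0.00723, and adjusted p = 0.183 with an estimated correlation) leaves that open as well.

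Strain variants carried along with the mutated allele near Tgfbr2 could give calls that have nothing to do with the mutation. Of the 79 genes called between Het and WT molars 0 lay within 10 Mb of Tgfbr2, where 291 of the other tested genes lie (Fisher's exact p = 0.63). None of the calls can thus be a change in a gene inside that window. Random positions would also place few called genes there, so the test itself decides nothing. Effects of such variants on genes outside the window were not tested. On chromosome 9 as a whole there were 4 (Fisher's exact p = 1). Strain variants elsewhere in the genome were not tested.

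The counts of genes were set beside those of 100 splits of the libraries of each age into groups of the same sizes, the real split included. The splits treat the libraries as independent, so they make no allowance for libraries that may share an animal. At P5, 2 splits, the real one included, gave as many genes as the 56 of the real split, the highest other giving 167. So small a share argues against chance, but 100 draws give it only roughly, and chance is not excluded. The arm of that other split was P5 WT 4, 5 and 6 with P5 Het 4, 5 and 6, which have prefixes 4 and 5, whereas the remaining P5 libraries have prefixes 3 and 4. Its count points to a structure of the samples, and with the prefix as a block 20 genes were higher and 49 lower between genotypes. At P11, 27 splits gave as many as the real 6, the highest other giving 515, and chance cannot be excluded. The arm of that other split was P11 WT 4 and 5 with P11 Het 2, 3 and 4 and held all 3 libraries rich in oral mucosa markers, again a structure of the samples; the prefix block gave 47 higher and 38 lower. Over both ages only the real split of those drawn (1 of 100) gave as many as its 37 genes. The highest other gave 14, which argues against chance if the libraries are independent. For the interaction 3 splits, the real one included, gave as many as the real 3 genes. Chance is not excluded, as the draws are few and the highest other gave 112, which points to a structure of the samples. Its P11 arm held 4 libraries of prefix 1 and 1 of prefix 2. At P11 this is the same division as that of the split that gave 515, so all 3 libraries rich in oral mucosa markers lay in the other arm. Prefix and oral mucosa are not told apart by it. The prefix block gave 23 higher and 6 lower in the interaction. In each age comparison only the real split (1 of 100) gave as many genes, the smallest share that the draw can give. The counts were 10633 in WT molars against 5902 for the highest other, and 10291 in Het molars against 2679. This argues against chance if the libraries are independent. No prefix occurs at both ages, so age and prefix cannot be told apart.

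For counts with the prefix block, genotypes were also regrouped within each age and prefix. At P11, 3 of the 60 possible splits gave as many genes as the real 85, the highest other giving 158, so chance cannot be excluded for the larger P11 count either. At P5, 2 of 90 splits, the real one included, gave as many as the real 69 genes. Over both ages and for the interaction 2 of 100 drawn splits, the real one included, gave as many as the real 85 and 29 genes. The highest other splits gave 445, 756 and 578 genes in these 3 comparisons, several times the real counts, which points to a structure of the samples within prefixes. Few splits reached the real counts, which argues against chance. Since a wrong grouping can exceed these counts so far, chance is not excluded.

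The genotype effect differed between P5 and P11 for 3 genes by the interaction test, with differences on the log2 scale of 1.66 for Steap1, 0.78 for F13a1 and 1.44 for Cldn20.

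Single libraries stood apart from the rest of their group in 23 of the 436 groups examined (5.28%), where chance gives about 1 in 20. The values are the gap to the nearest other library divided by the range of the group. P11 Het 2 was lowest in TGF-beta targets (0.818) and highest in Ttll11 (0.753), Gpha2 (0.848) and Wnt3a (0.787). P5 Het 4 was lowest in pulp and follicle genes (0.647) and Omd (0.648) and highest in oral keratinocyte markers (0.817) and Fst (0.788). These are the libraries that stood apart most often, 4 times each, and both had raised oral keratinocyte markers. P5 Het 5 was highest in muscle markers (0.85). P5 Het 3 was lowest in Amtn (0.67) and Cldn1 (0.682), and P5 Het 2 was highest in Col25a1 (0.693). P5 Het 6 was lowest in Top2a (0.655) and highest in Hrnr (1), of which it held the single count of the group. P5 WT 5 was lowest in erythroid markers (0.871) and highest in Steap2 (0.68). P5 WT 2 was highest in Col25a1 (0.641) and Thbs1 (0.63), P5 WT 4 lowest in Ibsp (0.626) and P5 WT 6 highest in C1qtnf7 (0.63). P11 WT 5 was lowest in Col8a1 (0.766) and Fst (0.713), and P11 Het 3 was highest in Pmepa1 (0.831).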

How the results depend on the processing

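Leaving out libraries with raised muscle or oral mucosa markers and using the marker scores as covariates were chosen only after the result was seen. The results are limited by groups of 5 or 6 libraries, by tissue around the tooth in some libraries, by library-name prefixes spread unevenly over the P5 groups and by depth, with at least 32904047 counts in each library. Of the counts of genes, 291 values stayed within 1.5 times and 85 did not; of the values of named genes, 5098 kept direction and call, 383 lost the call, 92 gained it and 5 turned direction. Of the values of lists, 795 were the same, 76 lost the call, 24 gained it and 65 turned direction. RLE size factors moved the median log2 fold change of all genes by less than 0.1 in every comparison. The library-name prefix lies within age, so its block could not be fitted for the age comparisons, and the mean of both ages and the interaction have no fit on 2 groups alone. The cause was not tested for any change below, except that fewer libraries or genes enter where some are left out.

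With each library left out in turn, the number of genes higher ranged from 10 to 17 at P5, 2 to 19 at P11, 6 to 18 over both ages, 2 to 8 for the interaction, 5061 to 5614 with age in WT and 4893 to 5419 in Het molars. The number lower ranged from 25 to 45, 0 to 7, 11 to 25, 0 to 2, 4804 to 5354 and 4643 to 5055. Klk4 at P11, at -0.06 with all libraries and uncalled throughout, ranged from -0.14 without P11 WT 4 to 0.03 without P11 Het 4, and turned also to 0.02 without P11 WT 3. The list tests without P5 Het 6 turned direction for BMP signalling (adjusted p = 0.907) and bone (0.861) in the interaction, osteoclasts (0.892) and TGF-beta components (0.872) at P5 and TGF-beta components with age in Het molars (0.992).

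Counts that moved by over 1.5 times with DESeq2 were 43 higher and 90 lower at P5, 70 and 37 at P11, 50 and 71 over both ages and 41 and 15 for the interaction. limma-voom gave 15 lower at P11 and 9 higher over both ages. With no filter 3 were lower at P11 and 1 in the interaction. On 2 groups alone 22 were higher at P5 and 0 at P11. The prefix block gave 47 higher and 38 lower at P11, 36 and 49 over both ages and 23 and 6 for the interaction. With marker scores as covariates 4 were lower at P11, 7 higher and 13 lower over both ages and 3343 lower with age in Het molars. Omitting the libraries with raised markers gave 9 and 11 at P5, 2 and 2 at P11 and 5 and 10 over both ages.

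The labels do not state that the replicate numbers pair the samples. Deviations of same-numbered libraries over 13598 genes had r between 0.04 and 0.46 at P5, with 4 of 6 libraries closest to their own number. At P11 r lay between -0.15 and 0.24, with 0 of 5. For P5 this is a hint of pairing from the data and not the design. The same-numbered libraries of those 4 replicates also share a library-name prefix. With the replicate number as a block 17 genes were higher and 48 lower at P5, 36 and 31 at P11, 34 and 53 over both ages and 18 and 9 for the interaction. Under the replicate block these uncalled lists turned direction: BMP signalling (adjusted p = 0.924) and odontoblast (0.946) in the interaction, cartilage with age in WT (0.965), secretory enamel over both ages (0.923) and TGF-beta components with age in Het molars (0.995). It gained the P5 odontoblast list (0.0472), the bone list over both ages (0.0479) and, in the interaction, the secretory (0.0108) and cell cycle lists (0.0393).

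With the prefix block, Tgfbr2 at P5 turned from 0.05 to -0.04, uncalled in both. Lists that turned direction were, in the interaction, BMP signalling (0.762), dental epithelium, muscle and TGF-beta targets (0.961 each) and bone (0.77). At P11 dental epithelium turned (0.919), over both ages iron (0.762) and nerve genes (0.948), and at P5 myeloid genes (0.492) and TGF-beta components (0.295). It gained the P5 erythroid list (0.0154), as did marker scores as covariates (0.0464) and leaving out P5 Het 6 (0.0192).

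With fry, lists that turned direction with age in Het molars were BMP signalling (0.917), dental epithelium (0.725) and TGF-beta components, which were called higher (0.0289). In WT molars they were BMP signalling (0.92) and TGF-beta components (0.431), in the interaction BMP signalling (0.99) and over both ages nerve genes (0.977).

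With marker scores as covariates, Hrnr (-0.28) and Krt4 (-2.06) turned with age in WT molars, as did BMP signalling (0.782), dental epithelium (0.306), muscle (0.679) and TGF-beta components (0.989). In Het molars BMP signalling (0.754), muscle (0.673), oral keratinocytes (0.883) and TGF-beta components (0.678) turned. The muscle and mucosa lists are the source of those covariates, so their own changes follow from the construction. Dental epithelium turned at P11 (0.98), muscle in the interaction (0.958), nerve genes over both ages (0.925), and oral keratinocytes (0.849) and TGF-beta components (0.958) at P5.

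When libraries with raised markers were left out, oral keratinocyte markers turned to higher in Het molars at P11 (7.81e-05), over both ages (0.00352) and in the interaction (0.000761), while at P5 they turned without a call (0.664). The libraries were picked by these markers, so that change follows in part from the construction. Uncalled at P11, these also turned: adhesion, secretory enamel and endoplasmic reticulum stress (0.997 each), dental epithelium (0.285), maturation enamel (0.126), erythroid cells (0.0874), muscle (0.74) and bone (0.53). In the interaction adhesion (0.371), cartilage and dental epithelium (0.393 each), erythroid cells (0.464), immediate early stress (0.8), and odontoblast and pulp genes (0.587 each) turned. Dental epithelium turned at P5 (0.989) and iron genes over both ages (0.747). With age, BMP signalling (0.985) and TGF-beta components (0.985) turned in Het and BMP signalling (0.706) and dental epithelium (0.492) in WT molars. Calls gained were BMP signalling (0.0269) and cartilage (0.0494) at P11, the P5 odontoblast list (0.0482) and, over both ages, BMP signalling (0.00783), maturation enamel (0.00587), erythroid cells (0.0408), osteoclasts (0.0107) and cartilage (0.00801).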

Other observations

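Steap2, the neighbour of Steap1 on chromosome 5 at a distance of 63.1 kb, was named after its values were seen. It encodes another member of the metalloreductase family and fell with Steap1 at P5, from 57.6 ± 3.13 CPM in WT to 40.4 ± 2.93 CPM in Het molars (SD, n = 6 each). All 6 Het libraries (37.6 to 44.7 CPM) lay below all 6 WT libraries (55.5 to 63.7 CPM), and its log2 fold change was -0.51 ± 0.08 (SE; adjusted p = 0.00241, between 6.46e-07 and 0.0132 over the alternatives). At P11 it was at 37.5 ± 5.83 CPM in WT and 35.7 ± 1.75 CPM in Het molars (SD, n = 5 each). Among the 79 called genes there were 6 pairs of neighbours within 1 Mb, against a median of 4 in 10000 random sets of as many tested genes (permutation p = 0.259, one-sided), a test chosen after Steap1 and Steap2 had been seen together.

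Members of the Wnt target and TGF-beta component lists moved in both directions over both ages. The lists were not called by camera, while fry's test for change in either direction, which compares with no other genes, gave adjusted p = 2.63e-06 and 0.00034. That test called 12 of the 24 lists over both ages, 5 of them uncalled by camera, among which were also bone (0.0027), dental epithelium and maturation enamel genes (0.0219 each). Adjusted over the Wnt list alone, Lef1 (0.23 ± 0.05 SE) was higher and Sfrp2 (-0.63 ± 0.13), Apcdd1 (-0.23 ± 0.07), an inhibitor of Wnt signalling, and Nkd2 (-0.18 ± 0.06), a feedback antagonist of the pathway, were lower. Over all genes Sfrp2 passed and the other 3 did not (adjusted p = 0.091, 0.287 and 0.355). Adjusted over the list of components alone, the signal transducer Smad3 (0.19 ± 0.06 SE) and the growth factor gene Gdf6 (0.85 ± 0.26), which stayed under 1 CPM in each library, were higher and Fst (-0.50 ± 0.15) was lower; over all genes their adjusted p-values were 0.306, 0.316 and 0.273. Of the bone list, Car3 (0.40 ± 0.11 SE) was higher and Mmp13 (-0.35 ± 0.08), Omd (-0.18 ± 0.06) and the mineralisation protein gene Dmp1 (-0.52 ± 0.17) were lower adjusted over the list alone (adjusted p = 0.239, 0.071, 0.332 and 0.362 over all genes). With the prefix block Dmp1 had an adjusted p of 0.00394 over all genes.

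Atp13a5, a transporter ATPase gene, had 25 counts in the 6 P5 WT libraries, with 0 in P5 WT 4, and 0 in the 6 P5 Het libraries. Set against a floor of 3 counts over the Het group, this is an 8.23-fold difference. That ratio makes no allowance for the counting error of the 25 counts. Its adjusted p of 0.0458 rose to 0.133 with the prefix block, 0.453 with limma-voom and 0.314 without the libraries with raised markers, and it lost the call in 18 of the 22 omissions of a library. At P11 it was at 11.4 ± 1.91 CPM in WT and 9.79 ± 3.41 CPM in Het molars (SD, n = 5 each). Of the features that are not mouse genes, those tested between genotypes gave exact permutation p-values from 0.0606 to 0.55.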
